A study of Escherichia coli with 9 samples.

How the data were processed

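RNA abundance was measured by RNA sequencing of total RNA in 9 libraries of Escherichia coli BL21(DE3), a laboratory strain that carries an inducible phage RNA polymerase gene and is widely used to express cloned genes. Per the labels' protocols, colonies from kanamycin plates were grown in seed cultures and diluted 100-fold into LB medium with 50 μg/mL kanamycin at 37 °C. At an optical density (OD) of 0.1 to 0.2 the cultures received 0.2 mM IPTG, an inducer of lac-controlled promoters, and the cultures of the AcK group also received 5 mM AcK. The cultures were then kept at 30 °C until harvest at an optical density of 0.5 to 0.6. The 3 groups, with 3 libraries each, were taken from the labels: a negative control, AcK, and NmGNAT. The characteristics field words AcK as something the cells were transformed with, whereas the protocol has it added to the medium, and the group was described by the protocol. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may in part be technical.

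The deposited table held FPKM (fragment counts scaled to gene length and library total), as its description in the labels names the unit, for 4443 genes in 9 columns. The column names differ from the sample titles, and each was matched to a library by its group word and replicate number, through the titles and the short names in the descriptions. All of the columns carry the vector name pRSFDuet. Those of the AcK group add kac with its dose, and those of the NmGNAT group add NmY and a number that the labels do not explain. The submitters' processing notes name HISAT2, RSEM and DESeq2 version 1.4.5, without roles; the genome build and annotation are not given in the sources used here. Raw counts were not analysed here, so the depth of each library is unknown and no counting interval can be given. Low values were searched for steps of whole reads: over the 36 library pairs, at most 1.43% of 210 low genes shared a ratio within a tolerance of 0.1%, so relative depth could not be recovered. Because FPKM is relative to the library total, a rise in a few abundant transcripts lowers the values of all others, which bears on how many genes appear higher or lower.

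All 4443 identifiers are locus tags that begin with gene-ECD_RS, and the deposited table does not pair them with gene names. The reference gene table used here describes the K-12 strain MG1655 and holds 4651 genes; 0 of the identifiers matched it. Genes are therefore given by tag, with no coordinates and no function. In the 39 gene lists fixed before the data were examined, 0 members could be matched to a tag. Neither camera nor fry was therefore run on them, and the panel of named genes fixed with them was not located. For the same reason the NmGNAT transgene was not analysed here, and the group labels were not checked against it.

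Values were transformed to log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the 9 libraries were tested (4267 genes). Group means of all 9 libraries were fitted together in limma version 3.58.1 under R version 4.3.3, with a variance trend and 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. The 3 comparisons were AcK against control, NmGNAT against control, and NmGNAT against AcK. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

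The rule for named genes, fixed before the data were examined, took the largest log2 fold changes among genes past the threshold that reached a mean of at least 10 FPKM in the higher group and whose 3 libraries of one group all lay above the 3 of the other. Without symbols it was held to 2 genes higher and 2 lower per comparison. Chance gives such a separation for 10% of genes in 3 against 3 libraries.

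The fit was tested on simulated data with 200 changed genes among 4267. Equal numbers of them rose and fell, with independent noise for each gene. The comparisons below called far more or far fewer genes than 200, so their recovered and false shares may differ. For AcK against control it recovered 29.4% of genes changed 1.25-fold, 61.4% of those changed 1.5-fold, 86.0% at 2-fold and 98.0% at 4-fold, and 3.94% of calls were false. For NmGNAT against control the recovered shares were 30.8%, 64.5%, 87.6% and 98.3%, with 4.70% false calls. For NmGNAT against AcK they were 32.2%, 66.2%, 83.8% and 97.7%, with 4.24% false calls. The search for genes that switch within a group found all 20 planted genes.

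The alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at 10 FPKM, median-of-ratios scaling, quantile normalization, equal sums, a fit of only the 2 groups compared, limma without the trend or with robust variance, a replicate block, each library left out in turn, and a minimum absolute log2 fold change of 1. Because AcK and NmGNAT were set against the same 3 control libraries, unchanged groups were simulated against those controls in 100 draws. The 3 controls could not be divided into groups of at least 2.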

Results

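The transcriptome of BL21(DE3) was compared in 3 libraries of control cells, 3 of cells supplied with 5 mM AcK and 3 of cells transformed with NmGNAT, in a series that the submitters place under AcK biosynthesis. FPKM values summed to 1324456 ± 10364 (SD, n = 3) in control, 1401184 ± 15829 in AcK and 1354446 ± 12611 in NmGNAT libraries. The read depth behind them is unknown. The median gene had 49.9 ± 1.21 FPKM (SD, n = 3) in control, 37.1 ± 1.66 in AcK and 50.2 ± 0.951 in NmGNAT libraries. The 100 most abundant genes held 51.8% ± 0.399 of the FPKM sum in control, 58.7% ± 0.371 in AcK and 53.2% ± 0.430 in NmGNAT libraries. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) between libraries of a group was 0.986 to 0.990. It was 0.983 to 0.988 between NmGNAT and control libraries and 0.921 to 0.929 between AcK and control libraries. No pair of libraries shared an identical value above 0.

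**Figure D1:**
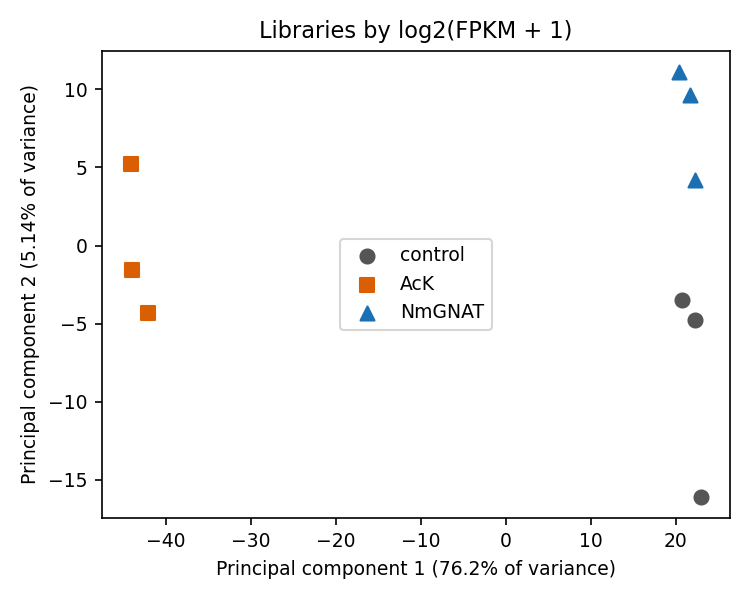
Principal components of log2(FPKM + 1) in the 9 libraries, 1 point per library, coloured by group. Component 1 holds 76.2% of the variance, and the AcK libraries lie at -44.2 to -42.2 on it while the 6 others lie at 20.4 to 23.0.

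The first comparison asked how cells supplied with AcK differed from control cells. Genes that fell in AcK reached larger changes than genes that rose. The gene with the tag gene-ECD_RS20550 went from 1731 ± 77.8 FPKM (SD, n = 3) in control to 4.77 ± 0.472 in AcK, a log2 fold change of -8.23 (SE 0.0751, limma, Benjamini-Hochberg adjusted p = 7.6e-13). The gene gene-ECD_RS20565 went from 1045 ± 63.1 to 5.69 ± 1.13 FPKM, a log2 fold change of -7.30 (SE 0.112, limma adjusted p = 7.5e-12). In the opposite direction, gene-ECD_RS18120 stood at 1.65 ± 0.0949 FPKM in control and 428 ± 7.60 in AcK, a log2 fold change of 7.34 (SE 0.0905, limma adjusted p = 3.5e-12). The gene gene-ECD_RS14705 had 37.6 ± 4.61 FPKM in AcK, while its control libraries held 0.0569, 0 and 0.362 FPKM. Its log2 fold change of 5.09 (SE 0.237, limma adjusted p = 3.3e-08) ran from 3.05 to 7.60 over the alternatives, pseudocounts included.

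The changes ran along the order of the locus tags. Of the 813 genes called with an absolute log2 fold change of at least 1, 264 lay in 45 stretches of 4 or more consecutive tested tags that moved the same way. Over 1000 shuffled gene orders the number in such stretches averaged 5.37 and was at most 22, and the permutation p of 0.001 is the smallest that 1000 shuffles can give. Shuffling treats each gene as a separate unit, whereas bacterial genes in operons are transcribed together. Any wide change would therefore be likely to exceed the shuffled orders. The p shows only that neighbouring tags moved together, and nothing particular to AcK. In 31 of the stretches the genes fell, with 11 genes in the longest, and in 14 they rose, with 13 in the longest. Stretches were counted on the deposited values alone, in which 234 genes were higher and 579 lower at this limit. With median-of-ratios scaling 385 were higher and 370 lower, so the balance of rising and falling stretches may depend on the scaling. The stretch that holds gene-ECD_RS20550 and gene-ECD_RS20565 has 7 genes with log2 fold changes of -8.23 to -2.94. The stretch with gene-ECD_RS14705 has 4 genes with log2 fold changes of 1.88 to 5.09. Across genes, the AcK log2 fold changes of neighbouring tags correlated at r = 0.56, against at most 0.0541 in the shuffled orders. These counts of stretches were made after the values had been seen.

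Of 4267 genes tested, 2714 (63.6%) passed the threshold in limma, 841 higher in AcK and 1873 lower. Of these, 234 higher and 579 lower genes changed by at least 1 on the log2 scale, and 41 and 144 by at least 2. After median-of-ratios scaling, 385 higher and 370 lower genes changed by at least 1, and 67 and 112 by at least 2. The balance of directions differed between scalings, of which median-of-ratios scaling and quantile normalization centre the fold changes near 0 by construction. With the deposited values 31.0% of calls were higher and the median log2 fold change of all genes was -0.26. With median-of-ratios scaling the median was 0.00 to 2 decimals, and 1291 genes were higher and 1241 lower (51.0% higher). With quantile normalization 1303 were higher and 1131 lower (53.5% higher). With equal sums 741 were higher and 2057 lower (26.5% higher). In all, 1773 calls kept their direction and passed the threshold under median-of-ratios scaling, quantile normalization and equal sums, 717 higher and 1056 lower.

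The balance of directions differed with expression level. Among 197 genes with a mean of 1000 FPKM or more, 109 were higher in AcK and 54 lower, with a median log2 fold change of 0.33, and 137 and 41 with median-of-ratios scaling. That mean includes the AcK libraries, so a rise in AcK can itself place a gene in this class. With classes set by the control mean, chosen after seeing the data, 87 of 195 genes were higher and 73 lower, with a median log2 fold change of 0.09, and 116 and 58 with median-of-ratios scaling. Among 1412 genes between 100 and 1000 FPKM, 389 were higher and 712 lower, or 612 and 473 with median-of-ratios scaling, which moves all genes of a library by the same factor. Among 1675 genes between 10 and 100 FPKM, 288 were higher and 856 lower, or 460 and 580 with median-of-ratios scaling. Among 983 genes between 1 and 10 FPKM, 55 were higher and 251 lower, or 82 and 147 with that scaling (982 genes tested).

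**Figure D2:**
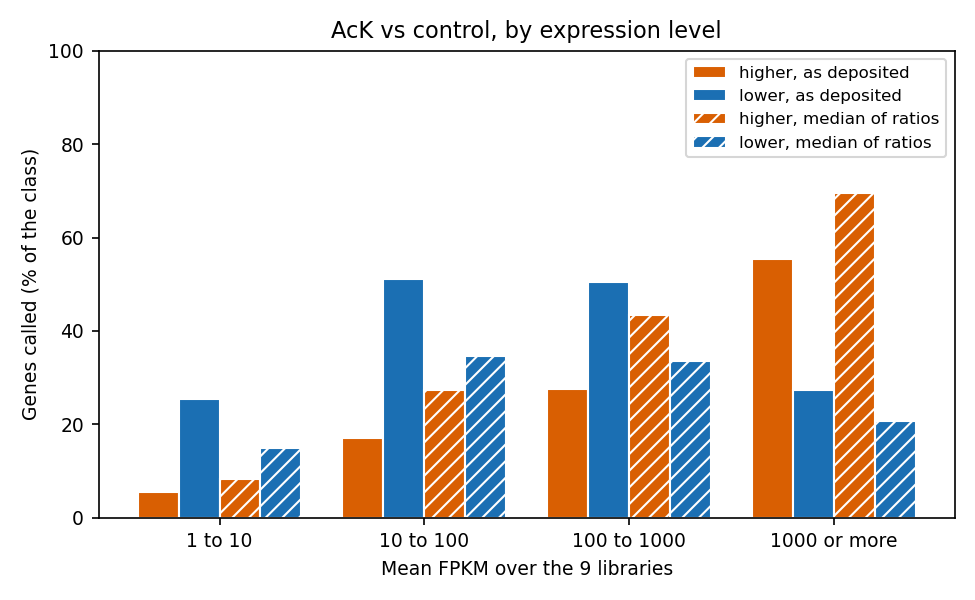
Percent of genes called higher or lower in AcK against control, by mean FPKM over the 9 libraries, for the deposited values (plain bars) and after median-of-ratios scaling (hatched bars). In the class of 1000 FPKM or more, 55.3% of genes were higher with the deposited values and 69.5% after rescaling, and the rescaling moved all genes of a library by the same factor. Set by the control mean instead, the class of 1000 FPKM or more had 44.6% of genes higher and 37.4% lower with the deposited values.

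The next comparison asked how cells with NmGNAT differed from control cells. Of the genes called, only 1 changed by more than 1 on the log2 scale. The gene gene-ECD_RS18120 had 387 ± 49.4 FPKM (SD, n = 3) in NmGNAT against 1.65 ± 0.0949 in control, a log2 fold change of 7.19 (SE 0.0905, limma adjusted p = 1.8e-11). The second largest change among called genes was that of gene-ECD_RS00190, which rose from 311 ± 15.3 to 519 ± 8.22 FPKM, a log2 fold change of 0.74 (SE 0.0585, limma adjusted p = 0.00032). The same gene was at 76.7 ± 4.23 FPKM in AcK. Among lower genes, gene-ECD_RS06075 went from 44.3 ± 2.71 to 27.4 ± 2.27 FPKM, a log2 fold change of -0.68 (SE 0.0952, limma adjusted p = 0.013). Its call was lost with adjusted p of 0.053 without control replicate 2, 0.082 without control replicate 3, 0.074 without NmGNAT replicate 2 and 0.063 without NmGNAT replicate 3. With a replicate block the call was lost at a limma adjusted p of 0.075. It was also lost, at 0.095, in the 6 libraries outside a split chosen after seeing the data, which is described in the closing observations. The log2 fold change was -0.69 to -0.62 in these fits. The gene gene-ECD_RS05745 went from 191 ± 3.06 to 130 ± 7.15 FPKM, a log2 fold change of -0.55 (SE 0.0549, limma adjusted p = 0.0019), and stood at 189 ± 2.86 FPKM in AcK. In the same 6 libraries its log2 fold change was -0.55 and its call was lost, with a limma adjusted p of 0.054.

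In this comparison limma called 31 of 4267 genes (0.727%), 10 higher and 21 lower, and 550 genes had an unadjusted p under 0.05. With no difference between the groups, a fraction of 0.05 of the 4267 genes would be expected there, which is fewer than 550. Whether that excess could arise from genes that vary together was not tested. The control and NmGNAT libraries also did not overlap on principal component 2. The simulated fit missed most of the smallest planted changes, so further small differences may have gone uncalled. All but 1 of the 31 changed by less than 1 on the log2 scale, with a median absolute value of 0.45. Of the 31 genes, 12 lay beside another called gene that moved the same way, in 4 stretches of 2 to 5 tags, against an average of 0.249 and at most 4 genes in 1000 shuffled orders. Across all genes tested, the NmGNAT log2 fold changes of neighbouring tags correlated at r = 0.0365, against at most 0.0981 in the shuffled orders. This r includes gene-ECD_RS18120, whose log2 fold change of 7.19 can lower it, and was not computed without that gene. The counts were not stable. By limma without a variance trend there were 3 higher and 4 lower, 6 of them among the 31. With a replicate block there were 3 higher and 2 lower. Without control replicate 1 there were 8 and 12, without control replicate 2 there were 5 and 14, without control replicate 3 there were 4 higher and 2 lower, without NmGNAT replicate 2 there were 3 and 2, and without NmGNAT replicate 3 there were 3 and 2. Without AcK replicate 1, which entered only the estimate of spread, there were 5 and 11, and without AcK replicate 3 there were 20 and 24.

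**Figure D3:**
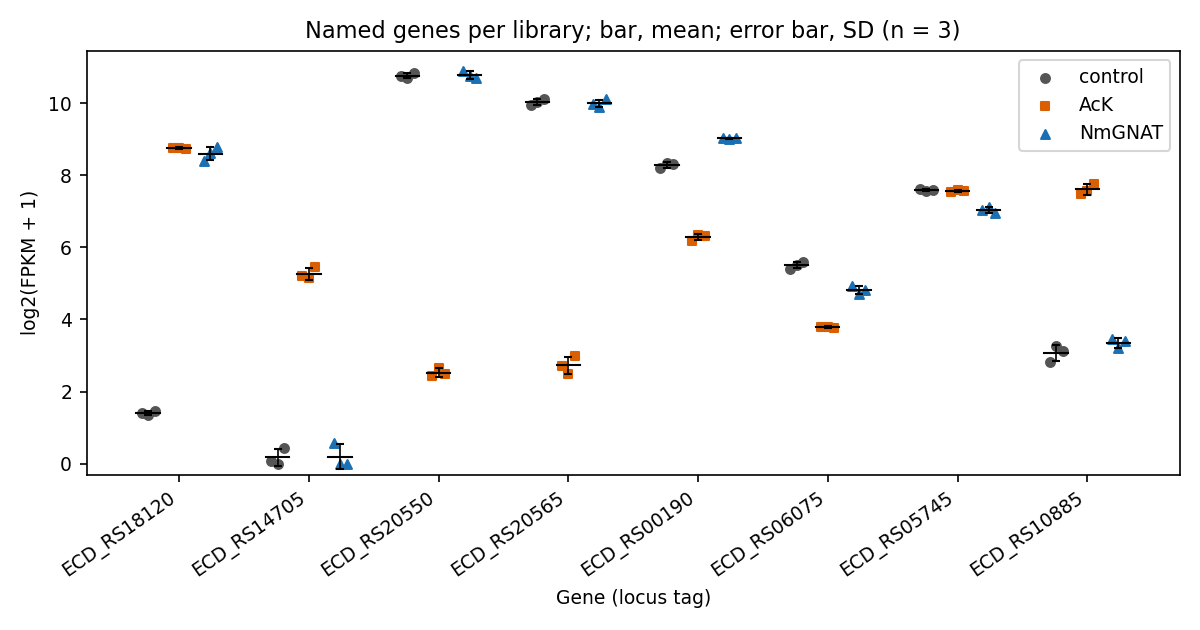
Expression of the named genes as log2(FPKM + 1) in each of the 9 libraries (points), with the mean and SD of each group (n = 3). For gene-ECD_RS18120 the AcK libraries (mean 428 FPKM) and the NmGNAT libraries (mean 387 FPKM) both lie far above the control libraries (mean 1.65 FPKM), and for gene-ECD_RS20550 the AcK libraries alone are low.

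The comparison of NmGNAT with AcK set cells carrying NmGNAT beside cells given AcK. It uses the same AcK libraries as AcK against control and is not independent of that comparison. Of the 2714 AcK calls, 2417 were called here too in the opposite sense. The genes gene-ECD_RS20550 and gene-ECD_RS20565 stood at 1759 ± 130 and 1018 ± 76.4 FPKM (SD, n = 3) in NmGNAT, with log2 fold changes over AcK of 8.25 (SE 0.0751, limma adjusted p = 7.0e-13) and 7.26 (SE 0.112, limma adjusted p = 9.1e-12). Against control their NmGNAT log2 fold changes were 0.02 and -0.04, and neither was called. For gene-ECD_RS14705, listed at 0 in NmGNAT replicates 2 and 3 and at 0.501 FPKM in NmGNAT replicate 1, the log2 fold change was -5.07 (SE 0.237, limma adjusted p = 3.2e-08), and it ran from -7.69 to -3.04 over the alternatives, pseudocounts included. The gene gene-ECD_RS10885 had 9.25 ± 0.925 FPKM in NmGNAT and 194 ± 19.6 in AcK, a log2 fold change of -4.25 (SE 0.136, limma adjusted p = 1.9e-09). The gene gene-ECD_RS18120 was not called here, with a log2 fold change of -0.15 (95% confidence interval -0.35 to 0.05, limma adjusted p = 0.17). In all, 1825 genes were higher in NmGNAT and 855 lower (68.1% higher), and with median-of-ratios scaling 1231 were higher and 1285 lower (48.9% higher). With quantile normalization 1128 were higher and 1338 lower (45.7% higher), and with equal sums 1959 and 776 (71.6% higher).

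The differences from control in AcK and in NmGNAT were then set against each other. Of the 31 genes called in NmGNAT, 13 were also called in AcK in the same direction, 16 in the opposite direction, and 2 were not called in AcK. Independent lists of these sizes would share 1.97 higher genes, where 2 were shared, and 9.22 lower genes, where 11 were shared. In opposite directions they would share 4.14 genes higher in AcK and lower in NmGNAT, where 9 were found, and 4.39 genes lower in AcK and higher in NmGNAT, where 7 were found. These expected numbers treat all 4267 genes alike. Of the NmGNAT calls, 7 higher and 17 lower had a mean of 100 to 1000 FPKM. In that class 27.5% of genes were higher in AcK and 50.4% lower. Between 1 and 10 FPKM the AcK shares were 5.60% and 25.5%, and NmGNAT had 0 calls. The expected numbers may therefore be too low. Unchanged groups simulated against the same controls shared 0 calls, with only 0.19 calls per draw to share, so they do not show how many calls shared controls add where AcK has 2714. Leaving out NmGNAT replicate 2 or NmGNAT replicate 3 brought the shared calls in the same direction to 2, control replicate 3 to 3, AcK replicate 1 to 6 and control replicate 2 to 8. Pearson's r of the log2 fold changes across the 4267 genes, which are not independent replicates, was 0.17, and 0.14 without gene-ECD_RS18120. Simulated unchanged groups gave r = 0.49 (0.35 to 0.58) from the shared controls alone. AcK changed no gene in those draws, whereas its real changes widen the spread of fold changes and so lower r. The simulated r therefore cannot serve as a baseline for the observed one. The covariance was 0.0478 against a simulated 0.0208 ± 0.00239 (SD over 100 draws), a difference of 0.0270. Without gene-ECD_RS18120 the covariance was 0.0350. The draws gave each gene independent noise, whereas deviations of neighbouring tested tags correlated at 0.153 on average. The simulated SD may therefore be too small. Part of the shared calls may come from the shared controls, which were too few to divide.

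**Figure D4:**
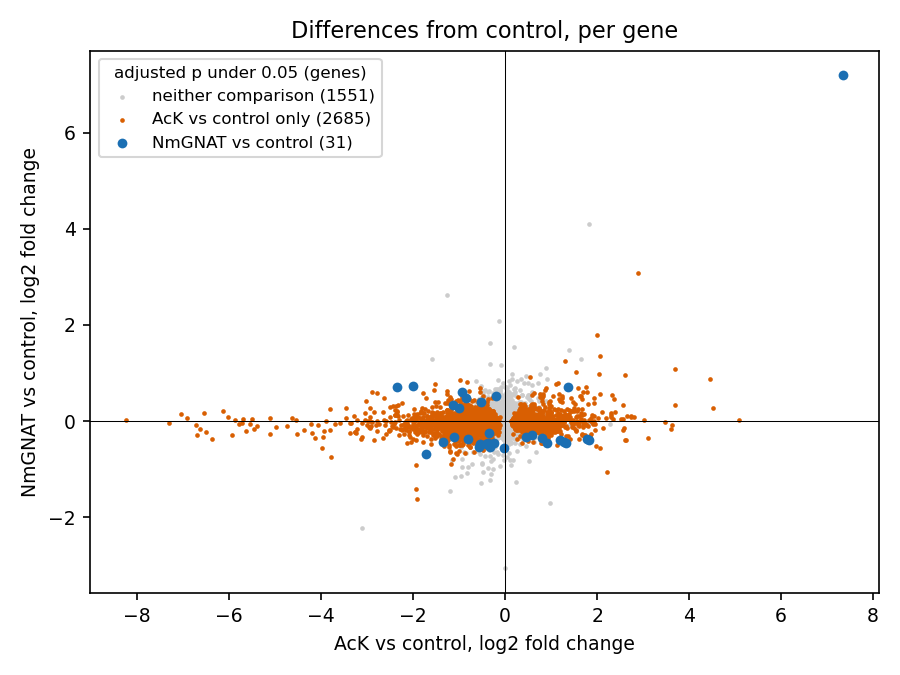
Log2 fold changes of each of 4267 genes in AcK against control (horizontal) and NmGNAT against control (vertical), coloured by which comparison called them. Called genes spread along the horizontal axis, and gene-ECD_RS18120 at 7.34 and 7.19 is the called gene far from both axes.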

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

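The alternatives named as chosen later were added after seeing the data, and all others were fixed before the data were examined. In AcK against control, the counts higher and lower were 1291 and 1241 with median-of-ratios scaling, 1303 and 1131 with quantile normalization, and 234 and 579 at an absolute log2 fold change of at least 1. In NmGNAT against AcK they were 1231 and 1285, 1128 and 1338, and 575 and 242 under the same 3 settings. Leaving out each library gave 774 to 843 higher and 1711 to 1865 lower in AcK against control, and 1678 to 1824 higher and 773 to 858 lower in NmGNAT against AcK. In NmGNAT against control, 10 higher and 21 lower became 3 and 4 by limma without a trend, 1 and 0 at an absolute log2 fold change of at least 1 (550 genes had an unadjusted p under 0.05), and 13 lower in a fit of only those groups. Leaving out each library gave 3 to 20 higher and 2 to 24 lower. The 13 genes called in the same direction in AcK and in NmGNAT against control became 8 in fits of only the 2 groups, 3 without a trend, and 2 to 18 with a library left out. The correlation of 0.17 became 0.20 and 0.14 with pseudocounts of 0.1 and 5, 0.14 at a mean FPKM of at least 10, and 0.13 to 0.23 with a library left out. Apart from the fewer genes or libraries in a fit, the cause was not tested. Deviations of same-numbered libraries correlated at r = -0.13 to 0.17 over 9 pairs, 2 of them over 0.1. Of 18 pairs with unlike numbers, 1 was over 0.1. The highest values were 0.17 for control and AcK replicate 2 and 0.13 for control and AcK replicate 3. Of the 9 libraries, 4 were closest to their own number. Such weak correlations cannot tell whether the number pairs the libraries. With a replicate block the counts were 821 and 1807 in AcK against control, 1781 and 832 in NmGNAT against AcK, 3 and 2 in NmGNAT against control, and 2 called in the same direction in both of these groups. Chosen later, the 6 libraries outside the split described under the other observations gave 7 higher and 2 lower in NmGNAT against control and 5 called in the same direction in AcK and NmGNAT. Also chosen later, that split as a covariate gave 13 and 27, and leaving out genes that switch within a group gave 12 and 23. In the class of 1000 FPKM or more, 109 higher and 54 lower in AcK became 87 and 73 with classes set by the control mean and 91 and 69 by the NmGNAT mean, both chosen later. Of 276 values of named genes under alternatives, 269 kept their direction and side of the threshold, 7 lost the call and 0 reversed. The named genes were picked as the largest changes in these data, most of them far from the threshold. This share therefore does not describe calls of smaller size, and all 7 losses fell in NmGNAT against control. The lost calls were gene-ECD_RS06075, with limma adjusted p of 0.075 under the replicate block and up to 0.095 elsewhere, and gene-ECD_RS05745, with 0.054 in those 6 libraries. Camera and fry were not run, since no member of a gene list could be matched to a tag, and the control libraries were too few to divide. Depth is unknown, so how far it limits weakly expressed genes cannot be said.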

Other observations

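The tests below were chosen after the patterns had been seen, except the rescalings and the splits of the libraries, which had been planned before the data were examined; the bounds for each were written after its value had been seen, apart from those for the fluctuation shared by neighbouring genes.

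Some genes switched between libraries of a single group. In 27 genes the range of log2(FPKM + 1) within a group was over 3. In 18 of these the high libraries averaged at least 20 FPKM and the low ones under 4 FPKM. In the 23 genes with a neighbouring tag at a mean of at least 10 FPKM, the neighbouring tags moved by a median of 0.12 on the log2 scale between the same libraries. In addition, 12 genes differed by limma between control replicate 3, AcK replicate 3 and NmGNAT replicate 1 and the 6 other libraries, 5 of them by at least 1 on the log2 scale. Among the 27 ways to take 1 library per group, no other way gave more than 2 genes. The gene gene-ECD_RS16645, chosen after its values were seen, averaged 1717 FPKM in those 3 libraries and 5214 in the 6 others. The split holds 1 library of each group.

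The first pattern is gene-ECD_RS18120, near 0 in the 3 control libraries and at means of 428 and 387 FPKM in the AcK and NmGNAT libraries. Loss of a stretch of genes in the control cultures is argued against by the 2 tags on either side, whose lowest control mean was 139 FPKM. A response of NmGNAT cells that follows the wide AcK response is argued against by the 184 other genes that AcK changed at least 4-fold, whose median NmGNAT log2 fold change in the AcK direction was 0.0681 (quartiles -0.06 and 0.19), against a median AcK change of 2.70. A quantification that reads single genes near 0 in individual libraries may also have fallen on the control group by chance: of the switching genes, 6 had 3 or 6 low libraries, for which 0.222 genes would be aligned with a group by chance. That number counts alignment with any of the 3 groups, and the number for low values in the control group alone is smaller. Either count by itself is too small to favour this reading, and neither excludes it. The 4 tags beside the gene had NmGNAT log2 fold changes of -0.13 to 0.093. Tags beside the switching genes were also steady, with a median shift of 0.12. The gene shares this trait with the switching genes, but a response of this gene alone would also give it. A response of this gene alone to AcK or NmGNAT was not tested and stays open.

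The second pattern is the breadth and the balance of the AcK difference. A few abundant genes shifting the scale is argued against as the cause of the breadth, since 2532 genes were called after median-of-ratios scaling, and a distortion by expression level likewise, since 2434 were called after quantile normalization. Whether the excess of lower genes comes from the scale or from the cells cannot be told apart: 51.0% of calls were higher after median-of-ratios scaling against 31.0% before, but that scaling centres the fold changes and so evens the counts whatever the cause. Among changes of at least 2 an excess of lower genes stayed after that scaling, with 67 higher and 112 lower. In the 10 splits of the 6 libraries, which are too few for a share under 0.05, only the real split, 1 of 10, reached 2714 calls (highest other 0), as did 1 of 10 for the 2680 calls of NmGNAT against AcK (highest other 2). The other splits mix libraries of both groups, so a wide group difference enters their spread and leaves few calls. They therefore do not show how many calls chance would give.

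The third pattern is that genes called in NmGNAT against control lie side by side. Independent false calls scattered over the genome are argued against by the 12 of 31 calls beside a call in the same direction, since shuffled orders gave at most 4. A fluctuation between libraries that neighbouring genes share may give the same picture: in the 8 adjacent pairs of called genes, deviations from the group means correlated at 0.779 on average, above the 0.153 of all neighbouring tested tags and the highest of 1000 draws of random pairs (0.471). Of the 10 splits, again too few for a share under 0.05, 1 reached the real 31 calls and the highest other gave 1. The other splits mix libraries of both groups here too, so any group difference enters their spread. An effect of NmGNAT on these genes stays open as well.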
